A study of Mus musculus with 9 samples.

How the data were processed

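PolyA RNA was sequenced from mouse bone marrow-derived macrophages, grown for 6 days with L929 supernatant, in 3 untreated, 3 IL-4 and 3 IL-27 libraries, per the labels' protocols. RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit, per the labels' protocols. The deposited counts are whole numbers per gene and library for 16200 genes, and fastp, HISAT2, HTSeq and the build GRCm39 are named in the submitters' processing notes without versions or settings. The deposited FPKM values are counts scaled by gene length and library total, made by a program that is not given in the sources used here. Dividing the deposited FPKM values by the counts gave gene lengths that were whole within 1e-06 bases for 100% of genes, so both tables hold the same counts on different scales. The counting strand, the annotation and the treatment of reads shared between genes are not given in the sources used here. Gene symbols are those of the deposited tables. No coordinates are used, and transcript GC content was taken from the longest transcript of each gene symbol in an older annotation for 15909 genes (98.2%). The 13 genes encoded in mitochondria were not analysed here.

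Counts were analysed in R 4.3.3 with edgeR 4.0.16, with all 9 libraries in 1 quasi-likelihood fit with a term for group and TMM factors (0.918 to 1.06). Genes were kept by filterByExpr with a minimum count of 10, which left 12587. The 3 comparisons were IL-4 with untreated, IL-27 with untreated and IL-27 with IL-4, and genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. Total counts ranged from 34577188 to 37951827 per library, and the common dispersion was 0.0272, a coefficient of variation of 0.165 between libraries. Standard errors of log2 fold changes were derived from the test, as the size of the log2 fold change over the square root of the quasi-likelihood F statistic. They are therefore approximate, above all for genes near 0 counts in a group. Group levels are means and SDs of TMM-normalised CPM. For some genes with few counts in a group, the ratio is given with an exact 95% counting interval. For a group at 0 counts only the lower limit is given. A floor of 3 counts over the group was used for such groups where a list median says so. The interval covers counting error only.

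Gene lists were fixed before the data were examined, as were the comparisons, the tests and most of the alternatives. They cover alternative activation, type I and gamma interferon targets, MHC class I and II, and cytokine signalling. Energy and lipid lists cover glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation, fatty acid oxidation and synthesis, cholesterol synthesis, and cholesterol efflux with LXR-linked genes. Others cover arginine, serine and one-carbon, pentose phosphate and antioxidant genes, inflammation, pain-linked mediators, cell cycle and ribosome biogenesis. Further lists cover the unfolded protein response, hypoxia, lysosome and macrophage identity. Lists of immediate early and heat shock genes and of other cell types served as checks on handling and purity. Camera (limma 3.58.1) tested lists of at least 5 tested members on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists tested. Medians give all tested members equal weight, and lists were also tested with an estimated correlation and with fry. Members were called from the adjustment over all genes, and the number passing when adjusted over the list alone is given beside it.

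Named genes followed a rule set beforehand. It takes the 8 largest fold changes in each direction with an adjusted p under 0.05, a mean of at least 5 CPM over the 6 libraries compared and no overlap between groups, leaving out unnamed gene models and pseudogenes. It adds the panel Arg1, Retnla, Chil3, Mrc1, Irf1, Socs1, Socs3, Il10, Cd274, Il4ra and Il27ra whatever the result, and up to 4 members of each list with the smallest adjusted p, and repeats a gene where it helps a comparison. Some genes that the rule names are not reported here. Genes outside these rules were chosen after their values were seen.

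The procedure was tested on simulated data made from the untreated profile, the fitted dispersions and the library sizes, with 50 genes changed at each fold size. Between IL-4 and untreated it recovered 0% of genes changed 1.25-fold, 30% at 1.5-fold, 58% at 2-fold and 88% at 4-fold. Between IL-27 and untreated it recovered 0%, 24%, 66% and 82% at the same sizes, and between IL-27 and IL-4 0%, 16%, 80% and 86%. False calls were 5 of 93, 5 of 91 and 6 of 97. The simulation changed far fewer genes than were called in the real comparisons, which makes an adjusted p under 0.05 harder to reach. The recovery rates therefore do not carry over to the real data. Genes were drawn independently, without the deviation that 2 of the real libraries shared, so neither does the rate of false calls. A gene that did not pass may still have changed, in the simulation even by 4-fold.

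Alternatives tried were RLE factors, library size only, no filter on low counts, a filter of CPM over 1 in 3 libraries, only the 2 groups compared, a replicate block, each library left out in turn, DESeq2 1.42.0, and limma on log2(FPKM + 1), on log2(FPKM + 0.1) and with a filter of FPKM over 0. After the data were seen, 3 more were added, namely both deviating libraries left out, offsets from 20 bins of transcript GC content, and IL-4 carry-over subtracted from the untreated libraries. The GC offsets were set against the mean of all 9 libraries, so they also remove GC-related differences between groups. Log2 fold changes correlated with GC content at Spearman -0.111 for IL-4 and -0.199 for IL-27 against untreated, and -0.0999 for IL-27 against IL-4. The overlap of the cytokines was compared with 20 simulated data sets in which the groups did not differ, and all 10 splits of the 6 libraries of each comparison were refitted. Figures and checks used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.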

Results

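Bone marrow-derived macrophages, cells grown from mouse marrow in medium with the supernatant of L929 fibroblasts as a source of macrophage growth factor, were profiled by polyA RNA sequencing after 6 days of culture. The 9 libraries fall into 3 groups of 3, namely untreated cells, cells given interleukin-4 (IL-4, 20 ng/ml for 12 h) and cells given interleukin-27 (IL-27, 100 ng/ml for 6 h). IL-4 is the cytokine classically used to induce alternative activation, and IL-27 is an IL-12 family cytokine that signals through Il27ra and Il6st. The title of the series names IL-27, metabolism, alternatively activated macrophages and inflammatory pain, so the fixed gene lists cover those themes. The labels give both cytokines in a treatment text shared by every sample, and do not say whether the IL-27 cells also received IL-4. The libraries held 34577188 to 37951827 counts each, and 14001 to 14326 of 16200 genes had at least 1 count. Levels are TMM-normalised CPM, given as mean ± SD over n = 3 libraries per group, and fold changes on the log2 scale carry their standard error. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Genes are named by the deposited symbols, and genome positions are not used here.

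A pair of libraries stood apart from the others of their groups. Pairs holding untreated replicate 2 or IL-4 replicate 1 gave a chi-square of 96.3 to 121 per gene, against 5.53 to 9.11 in the other pairs of the same group. Across 9527 genes at 5 CPM or more, which are not independent replicates, the deviations of these 2 libraries from their group means correlated at r = 0.900. In the tenth of genes with the lowest transcript GC content the median deviation was -0.41 in untreated replicate 2 and -0.44 in IL-4 replicate 1, and in the tenth with the highest it was 0.26 and 0.30 (log2). Among the gene lists, glycolysis had median deviations of 0.30 and 0.34 in these libraries and lysosomal genes 0.21 and 0.16. Cholesterol efflux and LXR-linked genes had 0.23 and 0.25, and antiviral genes -0.12 and -0.22. Both libraries stayed in the tests below.

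The first comparison, IL-4 against untreated cells, shows the alternatively activated state that the series sets IL-27 beside. Arg1, the arginase that turns arginine into ornithine and urea, stood at 5.26 ± 0.827 CPM in untreated and 472 ± 26.3 CPM in IL-4 libraries, an 89.7-fold rise (edgeR adjusted p = 6.99e-07). Chil3, a secreted chitinase-like protein, went from 24.99 ± 2.73 to 2213 ± 175 CPM (88.5-fold, edgeR adjusted p = 1.16e-06), and Retnla, a secreted resistin-like protein, from 1.13 ± 0.385 to 102 ± 20.2 CPM (90.1-fold, edgeR adjusted p = 3.23e-07). The mannose receptor Mrc1, already abundant at 300.1 ± 15.5 CPM, rose 4.55-fold to 1366 ± 95.3 CPM (edgeR adjusted p = 3.36e-07). Cell cycle genes, cholesterol synthesis genes and serine and one-carbon genes rose as groups, while inflammatory genes fell.

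In the list of alternative activation markers, of 26 tested members 24 rose, 0 fell and 2 did not pass, also when adjusted over the list alone, with a median log2 fold change of 4.08 (camera adjusted p = 4.42e-21). Its smallest p-values belonged to Pdcd1lg2, which encodes the PD-1 ligand PD-L2 (0.840 ± 0.0613 to 52.8 ± 4.61 CPM), and the cationic amino acid transporter Slc7a2 (23.2 ± 3.59 to 396 ± 12.8 CPM). Next came the VEGF receptor Flt1 (2.06 ± 0.546 to 91.6 ± 5.05 CPM) and the lectin Mgl2 (2.00 ± 0.706 to 97.1 ± 8.99 CPM). Because Chil3 and Retnla belong to families with close copies and the counting settings are not given in the sources used here, reads shared with Chil4 or Retnlg leave their exact levels uncertain. Outside the lists, the adhesion protein Cdh1 rose from 0.360 ± 0.123 to 42.1 ± 5.33 CPM, the interleukin-31 receptor subunit Il31ra from 0.164 ± 0.0787 to 17.7 ± 2.62 CPM and Rnase2a, an eosinophil-associated ribonuclease, from 0.229 ± 0.140 to 22.6 ± 7.50 CPM. Their edgeR adjusted p values were 2.97e-07, 1.26e-06 and 3.42e-05. Untreated Arg1, Chil3 and Retnla stood at 1.09%, 1.10% and 1.08% of their IL-4 levels in unscaled CPM. Untreated Cdh1, Il31ra and Rnase2a stood at 0.843%, 0.878% and 0.992%. These levels may be carried-over IL-4 material, so the sizes of all these rises are uncertain. An alternative chosen after seeing the data subtracted the lowest of these shares, 0.843%. It moved the log2 fold changes of Arg1, Chil3 and Retnla from 6.49, 6.47 and 6.49 to 8.64, 8.58 and 8.56.

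Among the 8 largest falls under IL-4, Adgre4, an adhesion receptor related to F4/80, dropped from 13.4 ± 2.88 to 0.282 ± 0.321 CPM, and Clec4n, the fungal mannan receptor dectin-2, from 20.2 ± 3.90 to 1.18 ± 0.148 CPM. The iron exporter Slc40a1 (ferroportin) fell 12.2-fold to 13.2 ± 3.05 CPM (edgeR adjusted p = 4.29e-07), the adrenergic receptor Adra1a 9.13-fold to 3.83 ± 0.423 CPM and the bacterial lipoprotein receptor Tlr2 7.32-fold to 7.86 ± 0.952 CPM (edgeR adjusted p = 3.21e-06). Fcrl1, Arl5c and Gpr162 were the others of these 8, at 9.10-fold, 8.34-fold and 8.33-fold.

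Among cytokine receptors, JAKs, STATs and feedback inhibitors, 6 of 38 tested members rose, 10 fell and 22 did not pass, also when adjusted over the list alone, and the list as a whole gave no call (camera adjusted p = 0.525). Its median log2 fold change was -0.07 while the mean was 0.21, and the test pointed down. The feedback inhibitors Cish and Socs1 rose 48.7-fold and 14.1-fold, to 41.9 ± 7.66 and 33.4 ± 4.79 CPM. Il6st, the signalling chain gp130 shared by IL-6 family receptors and IL-27, rose 2.80-fold (edgeR adjusted p = 1.92e-06), and the IL-27 receptor gene Il27ra went from 3.25 ± 0.834 to 8.05 ± 1.08 CPM (edgeR adjusted p = 0.00176). The IL-10 receptor Il10ra fell 2.11-fold. Irf1, Socs3 and Il10 did not pass, with log2 fold changes of 0.00 ± 0.14, -0.22 ± 0.17 and -0.36 ± 0.59, and the sign of Irf1 turned with the scaling. Il4ra fell by 0.39 on the log2 scale (edgeR adjusted p = 0.0443), a call that was lost on leaving out any 1 library except IL-4 replicate 1 (edgeR adjusted p from 0.0584 to 0.152). It was also lost without a filter on low counts and with only the 2 groups in the fit (edgeR adjusted p = 0.0551 and 0.110).

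Genes of the S, G2 and M phases were higher under IL-4: of 38 tested members 35 rose, 0 fell and 3 did not pass, also when adjusted over the list alone, with a median log2 fold change of 1.01 (camera adjusted p = 6.58e-18). The replication helicase genes Mcm6, Mcm4 and Mcm3 rose from 59.1 ± 3.53 to 162 ± 9.60, 28.0 ± 2.50 to 65.9 ± 5.19 and 47.7 ± 2.22 to 114 ± 15.3 CPM. The G1/S cyclin gene Ccne1 went from 6.03 ± 0.476 to 19.6 ± 1.21 CPM. In ribosome biogenesis 21 of 28 tested members rose, 0 fell and 7 did not pass, or 26 and 0 adjusted over the list alone (camera adjusted p = 1.14e-10). That list includes Myc, the transcription factor that drives growth, at 17.7 ± 2.36 CPM untreated and 73.1 ± 9.78 CPM under IL-4 (edgeR adjusted p = 6.40e-06), as well as the nucleolar protein genes Gar1, Nop56 and Nop2 with rises of 2.05-fold, 2.01-fold and 1.73-fold.

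For serine synthesis and one-carbon metabolism, of 18 tested members 13 rose, 1 fell and 4 did not pass, also when adjusted over the list alone, with a median of 0.83 (camera adjusted p = 4.27e-07). Phgdh, which opens serine synthesis, rose from 12.6 ± 0.960 to 86.0 ± 24.8 CPM, Psat1 in the same pathway from 30.2 ± 3.06 to 96.9 ± 5.82 CPM, and the mitochondrial folate enzyme genes Mthfd2 and Mthfd1l rose 3.64-fold and 2.46-fold. In cholesterol synthesis and uptake 13 of 24 tested members rose, 0 fell and 11 did not pass, or 16 and 0 adjusted over the list alone (camera adjusted p = 9.09e-07). The squalene epoxidase gene Sqle stood at 33.7 ± 3.98 and 74.8 ± 6.25 CPM, and Fdps and Stard4 rose 1.94-fold and 1.77-fold. In arginine and polyamine metabolism 7 members rose and 2 fell, with 10 of 19 not passing, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00328, adjusted p = 0.0532 with an estimated correlation). Besides Arg1 and Slc7a2, Gatm, which makes the creatine precursor from arginine, rose from 39.0 ± 1.31 to 386 ± 28.6 CPM and the arginine importer Slc7a1 from 20.8 ± 1.10 to 74.0 ± 3.99 CPM. For the unfolded protein response and targets of the stress-induced factor ATF4, of 24 tested members 10 rose, 0 fell and 14 did not pass, or 12 and 1 adjusted over the list alone (camera adjusted p = 5.45e-05, adjusted p = 0.109 with an estimated correlation). Asparagine synthetase Asns and the pseudokinase Trib3 rose 3.93-fold and 3.33-fold, and the folding enzyme Pdia4 and the factor Atf5 2.25-fold and 2.24-fold.

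Of 71 tested subunits of oxidative phosphorylation encoded in the nucleus, 28 rose, 0 fell and 43 did not pass (32 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 7.26e-09, adjusted p = 0.129 with an estimated correlation). Cytochrome c (Cycs) stood at 23.7 ± 1.60 CPM untreated and 43.5 ± 3.54 CPM under IL-4, and the complex I subunits Ndufa12 and Ndufa10 rose 2.11-fold and 1.44-fold. In the tricarboxylic acid cycle and pyruvate dehydrogenase 8 of 26 tested members rose, 1 fell and 17 did not pass, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000112, adjusted p = 0.184 with an estimated correlation). Idh3a, Sdhb and Fh1, all of the cycle, rose 2.12-fold, 1.41-fold and 1.67-fold, while cytosolic Idh1 fell from 358 ± 10.1 to 236 ± 21.5 CPM. For fatty acid oxidation 5 members rose and 1 fell, with 17 of 23 not passing, also when adjusted over the list alone (camera adjusted p = 0.0441, adjusted p = 0.280 with an estimated correlation). The coactivator Ppargc1b rose from 6.94 ± 0.429 to 21.9 ± 2.57 CPM and the electron transfer flavoproteins Etfb and Etfa 1.73-fold and 1.36-fold, while Ppard was lower by 1.84-fold. The list call was lost without untreated replicate 1, untreated replicate 3, IL-4 replicate 1, IL-27 replicate 1 or IL-27 replicate 3 (camera adjusted p from 0.0507 to 0.109). It was also lost with GC offsets, which were chosen after seeing the data, with the filter on CPM over 1 and with only the 2 groups in the fit (camera adjusted p = 0.145, 0.0563 and 0.0631).

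In glycolysis and glucose uptake of 26 tested members 7 rose, 4 fell and 15 did not pass, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.252), and leaving out untreated replicate 2 brought a call (camera adjusted p = 0.0445). Members went both ways, with the platelet-type phosphofructokinase Pfkp up from 65.1 ± 6.05 to 136 ± 16.5 CPM, the monocarboxylate transporter Slc16a1 up 1.91-fold, and the glycolysis-activating kinase Pfkfb3 down from 82.2 ± 7.84 to 48.9 ± 3.48 CPM. In fatty acid synthesis 3 of 14 tested members rose, 1 fell and 10 did not pass, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.459). The desaturase Scd2 was up 2.37-fold and the acetyl-CoA synthetase Acss2 down 2.73-fold. The pentose phosphate and antioxidant list had 1 member up and 5 down of 22, the same adjusted over the list alone (camera adjusted p = 0.248). Among the falls were catalase (Cat, 357 ± 14.1 to 209 ± 7.36 CPM) and glutathione reductase (Gsr, 135 ± 11.9 to 64.2 ± 7.89 CPM). Cholesterol efflux and LXR-linked genes fell as a list (camera adjusted p = 0.0312, adjusted p = 0.345 with an estimated correlation). Of 14 tested members 2 rose, 5 fell and 7 did not pass, also when adjusted over the list alone. This call was lost without untreated replicate 2, IL-4 replicate 2 or IL-4 replicate 3 (camera adjusted p = 0.1248, 0.0535 and 0.0801). GC offsets and the filter on CPM over 1 ended it too (camera adjusted p = 0.0875 and 0.0563). The cholesterol exporter Abca1 dropped from 219.6 ± 17.3 to 77.4 ± 3.40 CPM and Mylip, which marks the LDL receptor for degradation, from 69.0 ± 2.00 to 19.8 ± 1.70 CPM.

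Of the inflammatory genes, 3 rose, 14 fell and 8 of 25 did not pass (4 and 16 adjusted over the list alone). The list median was -0.77 (camera adjusted p = 0.000185). The rises were Ccl7 (3.46-fold), Cd40 (2.46-fold) and Ccl2 (2.43-fold), and the falls included the NF-kappa-B inhibitors Nfkbia and Tnfaip3. The costimulatory ligand Cd86 fell 3.17-fold, the inflammasome sensor Nlrp3 2.46-fold, the chemokine Cxcl16 2.61-fold and the NF-kappa-B cofactor Nfkbiz 5.13-fold. For antiviral interferon-stimulated genes of 42 tested members 1 rose, 20 fell and 21 did not pass, or 1 and 22 adjusted over the list alone (camera adjusted p = 1.05e-06, adjusted p = 0.113 with an estimated correlation). The falls included Rtp4 (8.48 ± 1.71 to 1.40 ± 0.316 CPM), Parp14 (138 ± 8.65 to 78.4 ± 5.49 CPM) and the oligoadenylate synthetases Oas2 and Oas3 (4.47-fold and 2.84-fold lower). Oas levels are uncertain because the family shares sequence. The interferon-gamma-type list gave 1 rise and 10 falls among 24 members (1 and 14 adjusted over the list alone; camera adjusted p = 8.77e-05, adjusted p = 0.0940 with an estimated correlation). Cd274, encoding PD-L1, was its 1 rise, from 104 ± 5.09 to 161 ± 6.56 CPM, while the Fc receptor genes Fcgr1 and Fcgr4 fell 2.67-fold and 1.61-fold. In MHC class II presentation 6 of 12 tested members rose, 0 fell and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00813, adjusted p = 0.132 with an estimated correlation). The peptide-loading genes H2-DMb1 and H2-DMb2 were up 1.91-fold and 2.93-fold and the invariant chain Cd74 1.49-fold, although H2 genes resemble each other and their split is uncertain. In MHC class I presentation 3 members rose and 2 fell, with 17 of 22 not passing, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.678). Class I members that rose included the immunoproteasome subunit Psmb10 (66.1 ± 14.0 to 119 ± 23.9 CPM) and the chaperone Calr (683 ± 47.0 to 911 ± 77.7 CPM).

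Macrophage identity and scavenger receptor genes fell as a list: of 27 tested members 3 rose, 8 fell and 16 did not pass, or 3 and 11 adjusted over the list alone (camera adjusted p = 0.00502, adjusted p = 0.340 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 dropped from 359 ± 13.3 to 57.8 ± 2.95 CPM, the fractalkine receptor Cx3cr1 from 42.8 ± 4.35 to 6.41 ± 0.782 CPM and the transcription factor Maf from 163 ± 19.4 to 53.7 ± 8.63 CPM. For lysosomal hydrolases and membrane proteins 1 member rose and 4 fell, with 26 of 31 not passing, also when adjusted over the list alone (camera adjusted p = 0.0441, adjusted p = 0.526 with an estimated correlation). That call was lost without untreated replicate 2 (camera adjusted p = 0.291) and on leaving out IL-4 replicate 2, IL-4 replicate 3 or any IL-27 library (camera adjusted p from 0.0513 to 0.151). Scaling by library size only and fitting only the 2 groups ended it too (camera adjusted p = 0.0518 and 0.0631). Npc2, a cholesterol carrier of the lysosome, fell 1.42-fold and the protease Ctsl rose 1.34-fold. Hypoxia-induced genes had 1 rise and 4 falls of 20, also when adjusted over the list alone (camera adjusted p = 0.121). The angiogenic factor Vegfa was down from 81.8 ± 2.58 to 26.7 ± 2.22 CPM and Ndrg1 down 2.15-fold. Among mediators linked to inflammatory pain and its resolution 5 of 24 tested members rose, 5 fell and 14 did not pass, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.448). Ptgs1, the constitutive cyclooxygenase, rose from 22.3 ± 0.658 to 137 ± 14.7 CPM (edgeR adjusted p = 5.37e-06), the prostaglandin receptor Ptger2 from 21.2 ± 2.38 to 38.8 ± 2.25 CPM, and Tnf fell from 12.7 ± 0.863 to 7.07 ± 0.611 CPM.

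Markers of other cell types were tested as well. Of the dendritic markers 1 rose and 2 fell of 7 (2 and 3 adjusted over the list alone; camera adjusted p = 0.510). Osteoclast markers gave 3 rises and 0 falls of 9, also adjusted over the list alone (camera adjusted p = 0.119). Fibroblast markers gave 0 rises and 2 falls of 10, also adjusted over the list alone (camera adjusted p = 0.0776). The fusion protein Ocstamp of osteoclasts rose from 2.90 ± 0.318 to 92.0 ± 13.4 CPM, the integrin Itgb3 from 131 ± 15.6 to 374 ± 69.6 CPM and Itgax, which macrophages also express, from 1475 ± 227 to 2344 ± 388 CPM. The fibroblast list reached a call on leaving out untreated replicate 2, untreated replicate 3, IL-4 replicate 1, IL-4 replicate 3, IL-27 replicate 1 or IL-27 replicate 2 (camera adjusted p from 0.0356 to 0.0485). So it did without a filter on low counts and with only the 2 groups in the fit (camera adjusted p = 0.0366 and 0.0308). Granulocyte, mast cell and basophil, T and NK cell, B cell and erythroid lists had fewer than 5 tested members each and no list test. They had 1 and 2, 1 and 0, 0 and 1, 0 and 0, and 1 and 0 members up and down (erythroid 1 and 1 adjusted over the list alone). The granulocyte median and mean differed in sign (-0.30 and 0.27), with the collagenase Mmp8 at 1.47 ± 0.256 and 8.94 ± 0.471 CPM. Immediate early and heat shock genes, a sign of handling stress, gave 6 rises and 1 fall of 21 (7 and 2 adjusted over the list alone; camera adjusted p = 0.119), with Ier3 up 4.23-fold and Zfp36 up 1.62-fold.

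Of 12587 genes tested, 1630 were higher and 1515 lower in IL-4 than in untreated libraries at an edgeR adjusted p under 0.05, and 499 and 430 of them by at least 2-fold. Camera called 17 of 28 lists, 11 up and 6 down, and 6 held with an estimated correlation, namely alternative activation, cell cycle, ribosome biogenesis, serine and one-carbon, cholesterol synthesis and inflammatory genes. Without untreated replicate 2 and IL-4 replicate 1, an alternative chosen after seeing the data, 3061 genes were higher and 2848 lower, and offsets for GC content, also chosen afterwards, gave 2508 and 2357. Fitting only these 2 groups called 2138 genes, 984 of them lower, and kept 67.4% of the calls above. The main fit also drew its dispersions from the IL-27 libraries. Those deviated less from their group mean (SD 0.0916 to 0.0989, log2) than the untreated and IL-4 libraries (0.149 to 0.300). With limma on log2(FPKM + 1), 262 and 144 genes changed at least 2-fold.

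**Figure D1:**
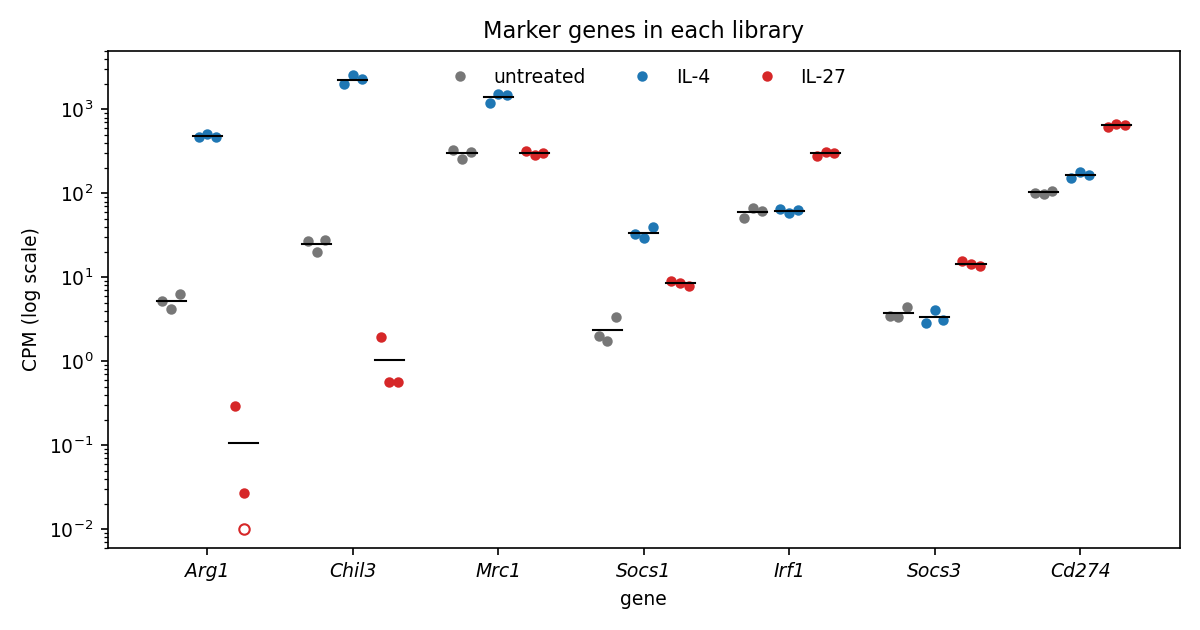
CPM (log scale) of 7 marker genes in each of the 9 libraries, with points for libraries, a black line for each group mean and an open circle at the bottom for a library with 0 counts. Arg1 and Chil3 were highest in the IL-4 libraries and lowest in the IL-27 libraries, and Irf1, Socs3 and Cd274 were highest in the IL-27 libraries.

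The IL-27 libraries against the untreated ones describe the response to IL-27, with the open point that the labels leave a joint treatment with IL-4 possible. Guanylate-binding proteins and immunity-related GTPases, which attack vacuoles that hold pathogens, showed the largest rises. Gbp2 went from 9.44 ± 0.632 to 539.7 ± 51.8 CPM (57.1-fold, edgeR adjusted p = 6.51e-09) and Iigp1 from 0.209 ± 0.197 to 38.4 ± 5.24 CPM (181-fold, edgeR adjusted p = 2.18e-06). Cd274 (PD-L1) rose 6.39-fold to 662 ± 29.1 CPM (edgeR adjusted p = 8.72e-08). Chil3 fell from 24.99 ± 2.73 to 1.04 ± 0.801 CPM (edgeR adjusted p = 1.11e-05) and Arg1 from 5.26 ± 0.827 to 0.109 ± 0.166 CPM (edgeR adjusted p = 1.80e-05). Without IL-27 replicate 1, which held 11 of the 12 Arg1 counts, the log2 fold change of Arg1 went from -5.54 to -8.26 and that of Chil3 from -4.58 to -5.43. Subtracting 0.843% of the IL-4 profile from the untreated libraries as possible carried-over material, chosen after seeing the data, shrank the falls to -3.39 and -2.47. Untreated Arg1 and Chil3 stood at 1.09% and 1.10% of their IL-4 levels, so part of their untreated level was bound to remain. Genes of the S, G2 and M phases fell as a group, while ribosome biogenesis genes rose.

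In the interferon-gamma-type list of 24 tested members 19 rose, 1 fell and 4 did not pass, also when adjusted over the list alone, with a median log2 fold change of 2.50 (camera adjusted p = 2.34e-14). Gbp3 rose from 5.604 ± 0.813 to 123 ± 11.7 CPM, the autophagy-linked GTPase Irgm1 from 41.8 ± 3.25 to 297 ± 12.5 CPM and Gbp5 from 1.72 ± 0.313 to 47.8 ± 8.38 CPM. Tgtp2, Gbp4 and Gbp6, near their floor in untreated libraries, reached 36.1 ± 1.99, 10.03 ± 1.11 and 10.4 ± 1.96 CPM. Gbp and Tgtp genes lie in families of close copies, so the split of reads among members is uncertain. Antiviral interferon-stimulated genes did not move as a list, since 8 of 42 tested members rose, 10 fell and 24 did not pass, or 9 and 11 adjusted over the list alone (camera adjusted p = 0.590). Its members went both ways, with the nucleic acid sensor Zbp1 up from 2.02 ± 0.796 to 14.9 ± 1.18 CPM, and Oas2, Rtp4 and Oas3 down 8.05-fold, 4.27-fold and 2.38-fold. For MHC class I presentation 6 members rose and 3 fell, with 13 of 22 not passing, also when adjusted over the list alone (camera adjusted p = 0.329). The class I transactivator Nlrc5 was up 3.80-fold, the peptide transporter Tap1 up 3.07-fold and Tapbpl up 2.53-fold. Class II presentation had 2 rises and 1 fall of 12, also adjusted over the list alone (camera adjusted p = 0.252), namely the class II transactivator Ciita and H2-Aa (1.71-fold and 1.51-fold up) and the factor Rfx5 (1.67-fold down).

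Signalling genes changed in both directions: of 38 tested members 10 rose, 8 fell and 20 did not pass, or 12 and 10 adjusted over the list alone (camera adjusted p = 0.719). Socs3, a feedback inhibitor of gp130 signalling, rose from 3.78 ± 0.502 to 14.9 ± 0.922 CPM (edgeR adjusted p = 1.87e-05), and Socs1 from 2.36 ± 0.759 to 8.64 ± 0.519 CPM (edgeR adjusted p = 0.000125). Irf1, an early interferon-response factor, went from 60.9 ± 12.1 to 305 ± 18.1 CPM (edgeR adjusted p = 3.92e-06). The interferon-gamma receptor Ifngr1 fell 2.28-fold and the IL-6 receptor Il6ra 2.47-fold. Il4ra, the IL-4 receptor chain, rose 1.49-fold to 107 ± 6.02 CPM (edgeR adjusted p = 0.00583), while Il27ra (-0.20 ± 0.22), Mrc1 (0.04 ± 0.09) and Il10 (-1.59 ± 0.64, under 1 CPM in every group) did not pass on the log2 scale. Il10 passed with GC offsets and with limma on FPKM over 0 (adjusted p = 0.0499 by edgeR and 0.0314 by limma).

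Of the alternative activation markers, 5 rose, 9 fell and 12 of 26 did not pass, the same adjusted over the list alone, and the list gave no call (camera adjusted p = 0.316). Its median log2 fold change was -0.41, and -0.08 with members that had a group at 0 counts set to the bound of 3 counts over the group. Retnla had 1 count in the IL-27 libraries together and 119 in the untreated ones, a ratio of 126 (exact 95% counting interval 22.1 to 5005). Its call was lost once the lowest untreated share of the IL-4 profile was subtracted from the untreated libraries (edgeR adjusted p = 0.0857), an alternative chosen after seeing the data. Klf4, a transcription factor of alternative activation, and Slc7a2 rose 2.81-fold and 2.31-fold. Most of these markers had risen in the IL-4 libraries. The list as a whole therefore argues against IL-4 having acted in the IL-27 cells as it did in the IL-4 libraries. It cannot show whether IL-4 was given and had no such effect.

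Cell cycle genes fell: 0 of 38 tested members rose, 31 fell and 7 did not pass, or 1 and 33 adjusted over the list alone, with a median of -1.39 (camera adjusted p = 1.72e-16). The mitotic cyclin gene Ccnb2 dropped from 25.1 ± 2.70 to 2.68 ± 0.418 CPM, the ubiquitin-conjugating enzyme Ube2c of mitotic exit from 22.97 ± 2.71 to 3.00 ± 0.258 CPM, and the checkpoint kinase Bub1b and the kinesin Kif20a 6.14-fold and 5.23-fold. Among the 8 largest falls of all genes were also the spindle and centromere genes Aspm and Cenpf (9.76-fold and 9.23-fold). The other large falls were in Hpgd, which inactivates prostaglandins (86.8 ± 15.7 to 3.55 ± 0.755 CPM, edgeR adjusted p = 1.29e-06), Zfyve28 (12.4-fold), Fgd2 (9.61-fold) and Adgre4 (12.1-fold). Hcar2, the receptor for niacin and beta-hydroxybutyrate, was the 1 gene outside the GTPase families among the 8 largest rises, from 0.466 ± 0.0298 to 12.5 ± 1.46 CPM.

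For ribosome biogenesis of 28 tested members 15 rose, 1 fell and 12 did not pass, also when adjusted over the list alone (camera adjusted p = 5.14e-05), and Nop14, Nolc1, Gar1 and Nop56, all nucleolar, rose 1.93-fold, 2.03-fold, 1.68-fold and 1.68-fold. In the unfolded protein response and ATF4 list 12 members rose and 3 fell, with 9 of 24 not passing, also when adjusted over the list alone (camera adjusted p = 0.000355, adjusted p = 0.238 with an estimated correlation). Trib3 went from 4.002 ± 0.234 to 77.6 ± 4.29 CPM, Asns from 10.1 ± 1.37 to 106 ± 3.69 CPM, Atf4 itself from 129.6 ± 3.09 to 477 ± 12.6 CPM and the leucine transporter Slc7a5 from 13.3 ± 0.840 to 102 ± 5.18 CPM. The folding genes Hspa5 and Pdia4 of the same list, picked after their values were seen, fell (-0.47 ± 0.07 and -0.45 ± 0.10 on the log2 scale). Serine synthesis and one-carbon genes rose as a list, where 10 of 18 tested members rose, 2 fell and 6 did not pass, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00460, adjusted p = 0.120 with an estimated correlation). Mthfd2 was up 6.09-fold, the serine transporter Slc1a4 4.37-fold, Phgdh 3.30-fold and Psat1 2.00-fold. In arginine and polyamine metabolism of 19 tested members 8 rose, 4 fell and 7 did not pass, also when adjusted over the list alone (camera adjusted p = 0.346). Slc7a1 was up from 20.8 ± 1.10 to 187 ± 4.36 CPM and Gatm down from 39.0 ± 1.31 to 11.4 ± 0.955 CPM.

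For glycolysis 6 of 26 tested members rose, 5 fell and 15 did not pass, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.790). The kinase Pfkfb3 and transporter Slc16a1 rose 2.17-fold and 2.76-fold while Pdk1, which shuts pyruvate dehydrogenase, and Pfkm fell 2.44-fold and 2.87-fold. In the tricarboxylic acid cycle 1 member rose and 6 fell, with 19 of 26 not passing, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.195), including Idh1 (358 ± 10.1 to 131 ± 8.58 CPM) and Mdh1 (1.57-fold lower). Few oxidative phosphorylation subunits passed, with 2 up, 3 down and 66 of 71 not passing and 0 up and 0 down adjusted over the list alone (median -0.20, camera adjusted p = 0.108), and scaling by library size only brought a call (camera adjusted p = 0.0392). For fatty acid oxidation of 23 tested members 4 rose, 7 fell and 12 did not pass, or 5 and 13 adjusted over the list alone (camera adjusted p = 0.153). The dehydrogenase genes Hadh and Hadha were down 1.72-fold and 1.40-fold and Ppargc1b up 1.79-fold. Fatty acid synthesis fell: 0 members rose and 5 fell, with 9 of 14 not passing, or 0 and 8 adjusted over the list alone (camera adjusted p = 0.00659, adjusted p = 0.286 with an estimated correlation). Scd2 went from 159 ± 21.8 to 73.5 ± 7.56 CPM and Acss2 was 2.89-fold lower. Cholesterol synthesis gave 4 rises and 5 falls of 24 (4 and 6 adjusted over the list alone; camera adjusted p = 0.556), with Insig1 up 1.35-fold and Mvk down 1.82-fold. In pentose phosphate and antioxidant genes 3 of 22 tested members rose, 8 fell and 11 did not pass, or 3 and 10 adjusted over the list alone (camera adjusted p = 0.108). The cystine importer Slc7a11 was up from 39.6 ± 8.25 to 184 ± 16.1 CPM and the entry enzyme G6pdx of the pentose pathway down from 235 ± 35.9 to 99.9 ± 1.84 CPM. Cholesterol efflux and LXR-linked genes fell as a list (camera adjusted p = 0.00659, adjusted p = 0.406 with an estimated correlation). Of 14 tested members 1 rose, 5 fell and 8 did not pass, also when adjusted over the list alone. The falls included Cyp27a1 (2.78-fold) and Abca1 (2.15-fold), and Ch25h was the 1 rise (3.15-fold). Leaving out untreated replicate 2 and IL-4 replicate 1 together, or using GC offsets, ended the LXR call (camera adjusted p = 0.0546 and 0.102).

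Inflammatory genes did not move together: 6 members rose and 6 fell, with 13 of 25 not passing, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.790). Cd86 rose from 7.33 ± 0.735 to 36.5 ± 0.868 CPM, Il1a 3.11-fold and the inducible cyclooxygenase Ptgs2 from 1.251 ± 0.519 to 7.36 ± 1.76 CPM. Il1b had 262 counts in the untreated and 1 in the IL-27 libraries, a ratio of 277 (exact 95% counting interval 49.2 to 10970.0). In the list of pain-linked mediators 4 of 24 tested members rose, 7 fell and 13 did not pass, also when adjusted over the list alone (camera adjusted p = 0.364). The IL-1 receptor antagonist Il1rn was up from 5.34 ± 1.89 to 39.9 ± 4.57 CPM, the ATP-gated channel P2rx7 down 1.69-fold and Ptgs1 down 2.36-fold. Hypoxia-induced genes rose, where of 20 tested members 10 rose, 2 fell and 8 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0220, adjusted p = 0.238 with an estimated correlation). Vegfa and Hilpda were up 1.82-fold and 2.17-fold. Macrophage identity genes fell, where 2 of 27 tested members rose, 12 fell and 13 did not pass, or 2 and 14 adjusted over the list alone (camera adjusted p = 0.00569, adjusted p = 0.445 with an estimated correlation). The falls included the efferocytosis receptor Mertk (206 ± 16.4 to 91.5 ± 2.19 CPM), Maf (2.57-fold) and the folate receptor Folr2 (4.25-fold). With untreated replicate 2 and IL-4 replicate 1 left out, hypoxia and identity lists no longer passed (camera adjusted p = 0.0546 and 0.0680). GC offsets ended the hypoxia call (camera adjusted p = 0.0674). Lysosomal genes gave 6 rises and 1 fall of 31, also adjusted over the list alone (camera adjusted p = 0.108). The cysteine protease genes Ctsk and Ctsl were up 1.97-fold and 1.77-fold, and the list was called up without untreated replicate 2, without both deviating libraries and with GC offsets (camera adjusted p = 0.00594, 0.000509 and 0.0277).

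Fibroblast markers rose with IL-27: of 10 tested members 5 rose, 0 fell and 5 did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00460, adjusted p = 0.412 with an estimated correlation). The matrix proteoglycan Dcn stood at 7.65 ± 1.81 CPM untreated and 34.6 ± 11.6 CPM under IL-27 (edgeR adjusted p = 0.000147), the collagen genes Col1a2 and Col3a1 rose 1.64-fold and 2.05-fold and the receptor Pdgfrb 2.38-fold. The summed CPM of the list was 730 to 881 in untreated, 603 to 752 in IL-4 and 1097 to 1380.0 in IL-27 libraries. Osteoclast markers gave 4 rises and 2 falls of 9, also adjusted over the list alone (camera adjusted p = 0.346). Itgb3 was up 3.20-fold and Tnfrsf11a, the receptor RANK, down 1.64-fold. Dendritic markers gave 0 rises and 1 fall of 7, also adjusted over the list alone (camera adjusted p = 0.384), with Tcf4 down 1.55-fold. In the granulocyte, mast cell and basophil, T and NK cell, B cell and erythroid lists 1 and 2, 0 and 0, 0 and 0, 1 and 1, and 0 and 0 members passed up and down. Among them S100a8 went from 4.09 ± 0.599 to 8.32 ± 0.723 CPM and the G-CSF receptor Csf3r, also a myeloid gene, from 108 ± 17.3 to 47.9 ± 0.875 CPM. Immediate early and heat shock genes fell as a list, where 2 members rose and 8 fell, with 11 of 21 not passing, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.00699, adjusted p = 0.286 with an estimated correlation). Btg2, the chaperone Hspa8 and Fos were down 3.47-fold, 2.08-fold and 1.99-fold. The list call was lost with the 2 deviating libraries left out and with GC offsets (camera adjusted p = 0.0680 and 0.345).

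In all, 1766 genes were higher and 1904 lower under IL-27 than in untreated libraries by edgeR, 585 and 661 of them by at least 2-fold, and 11 of 28 lists were called by camera, 6 up and 5 down. With an estimated correlation the interferon-gamma-type, cell cycle and ribosome biogenesis lists kept their calls. Leaving out untreated replicate 2 and IL-4 replicate 1, chosen after seeing the data, gave 3089 higher and 3224 lower genes, and limma on log2(FPKM + 1) called 234 and 288 at 2-fold or more.

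**Figure D2:**
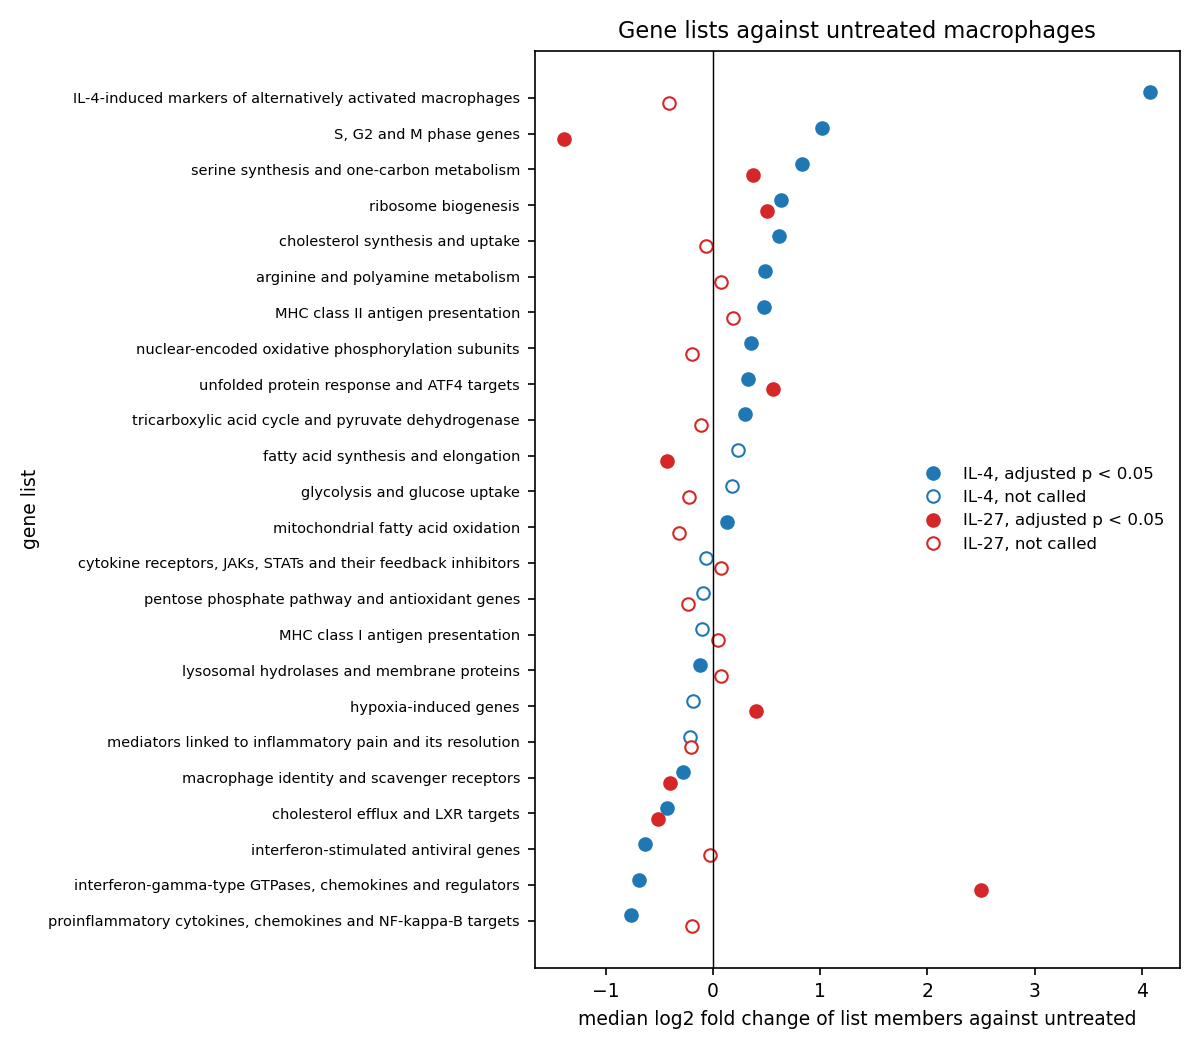
Median log2 fold change against untreated libraries (x axis) of 24 gene lists (y axis), blue for IL-4 and red for IL-27, filled where the camera adjusted p was under 0.05. S, G2 and M phase genes lie at 1.01 under IL-4 and -1.39 under IL-27, and interferon-gamma-type genes at -0.69 and 2.50.

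The direct comparison of IL-27 with IL-4 places the cytokines side by side, with the limit that IL-27 acted for 6 h and IL-4 for 12 h, so that cytokine, dose and time differ together. Retnla had 1 count in the IL-27 and 11540.0 in the IL-4 libraries, a ratio of 11630.0 (exact 95% counting interval 2088 to 459500.0), and Arg1 12 against 53501, a ratio of 4495 (2573 to 8699). Chil3 was 2120.0-fold lower and Mrc1 4.43-fold lower under IL-27 (edgeR adjusted p = 7.87e-08 and 1.29e-07). Among the IL-27 libraries, replicate 1 held the only Retnla count, 11 of the 12 Arg1 counts and 72 Chil3 counts, against 21 Chil3 counts in each of the others. Without it the log2 differences of Retnla, Arg1 and Chil3 went from -12.99, -12.03 and -11.05 to -14.86, -14.75 and -11.90, so the sizes of these ratios are uncertain. In the other direction Gbp2 was 69.7-fold higher, Irf1 5.00-fold and Cd274 4.10-fold (edgeR adjusted p = 3.84e-09, 1.38e-06 and 9.72e-08). Genes of the S, G2 and M phases were lower under IL-27 as a group, and interferon-gamma-type genes higher.

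In the list of alternative activation markers, of 26 tested members 1 was higher, 22 were lower and 3 did not pass, also when adjusted over the list alone, with a median of -3.98 (camera adjusted p = 2.17e-13). Pdcd1lg2 was 52.8-fold lower, Flt1 59.2-fold and Cish 205-fold. Cdh1, Il31ra and Map2, a microtubule-associated protein, were also among the 8 largest differences, at 42.1 ± 5.33, 17.7 ± 2.62 and 19.4 ± 4.06 CPM under IL-4 and 0.274 ± 0.141, 0.0455 ± 0.0418 and 0.210 ± 0.182 CPM under IL-27. Rnase2a had 0 counts under IL-27 against 2526 under IL-4, a ratio with an exact 95% lower limit of 689.8. Interferon-gamma-type genes stood higher, where 23 of 24 tested members were higher, 0 were lower and 1 did not pass, also when adjusted over the list alone (camera adjusted p = 1.04e-16). Gbp3, Gbp5 and Irgm1 were higher by 35.3-fold, 65.0-fold and 10.9-fold. Iigp1 had 4204 counts against 4, a ratio of 1043 (exact 95% counting interval 407 to 3828), and Gbp4 1098 against 2, a ratio of 545 (150.4 to 4503). Tgtp2, Gbp6, Hcar2 and Efcc1 completed the largest rises, at 36.1 ± 1.99, 10.4 ± 1.96, 12.5 ± 1.46 and 15.1 ± 2.14 CPM under IL-27 against 0.213 ± 0.0797, 0.212 ± 0.229, 0.240 ± 0.0567 and 0.345 ± 0.126 CPM under IL-4.

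For antiviral interferon-stimulated genes of 42 tested members 18 were higher, 4 were lower and 20 did not pass, or 19 and 4 adjusted over the list alone (camera adjusted p = 0.00270, adjusted p = 0.298 with an estimated correlation). Viperin (Rsad2) was 6.62-fold higher under IL-27, Ifit2 4.57-fold, Slfn5 2.78-fold and Zbp1 6.76-fold. Inflammatory genes were higher too, where 13 members were higher and 5 were lower, with 7 of 25 not passing, also when adjusted over the list alone (camera adjusted p = 0.0159, adjusted p = 0.153 with an estimated correlation). Cd86 was at 2.31 ± 0.337 CPM under IL-4 and 36.5 ± 0.868 under IL-27, Cxcl16 3.44-fold higher and Tnf 2.86-fold higher. In MHC class I presentation 7 of 22 tested members were higher, 5 were lower and 10 did not pass, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.334). Nlrc5 and Tap1 were 4.76-fold and 3.33-fold higher and Calr 1.71-fold lower. In class II 1 member was higher and 5 were lower, with 6 of 12 not passing, also when adjusted over the list alone (camera adjusted p = 0.240), with H2-DMb1 and Cd74 1.71-fold and 1.39-fold lower. Of the signalling genes 12 were higher and 10 lower of 38 (13 and 10 adjusted over the list alone; camera adjusted p = 0.766), and the mean of -0.16 differed in sign from the median of 0.10 and the test. Il27ra and Il6st, the chains of the IL-27 receptor, were 2.85-fold and 2.84-fold lower under IL-27, Il4ra 1.95-fold higher, Socs1 3.86-fold lower and Socs3 4.58-fold higher, while Il10 did not pass (log2 -1.23 ± 0.65).

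Cell cycle genes were lower nearly throughout: of 38 tested members 0 were higher, 37 were lower and 1 did not pass, also when adjusted over the list alone, with a median of -2.84 (camera adjusted p = 4.95e-24). Ube2c stood at 38.0 ± 3.92 CPM under IL-4 and 3.00 ± 0.258 under IL-27, Ccnb1 at 41.9 ± 3.48 and 4.49 ± 0.809 CPM, and Bub1b and Kif20a were 9.57-fold and 8.30-fold lower. Oxidative phosphorylation subunits were lower, with 0 up, 49 down and 22 of 71 not passing (0 and 54 adjusted over the list alone; median -0.53, camera adjusted p = 2.20e-09, adjusted p = 0.153 with an estimated correlation). Examples are the ATP synthase subunits Atp5g3 and Atp5pb (1.80-fold and 1.46-fold) and Cox7b (1.88-fold). In the tricarboxylic acid cycle 0 members were higher and 18 were lower, with 8 of 26 not passing, or 0 and 20 adjusted over the list alone (camera adjusted p = 6.14e-05, adjusted p = 0.183 with an estimated correlation). Lower members included Idh2 (95.8 ± 22.7 CPM under IL-4, 34.0 ± 1.35 under IL-27), Fh1 (2.26-fold lower) and Idh3a (2.02-fold lower). For fatty acid oxidation 2 of 23 tested members were higher, 15 were lower and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00314, adjusted p = 0.153 with an estimated correlation). Hadh, Hadha and Etfb were 2.02-fold, 1.66-fold and 2.15-fold lower. Cholesterol synthesis was lower, where of 24 tested members 0 were higher, 15 were lower and 9 did not pass, or 1 and 15 adjusted over the list alone (camera adjusted p = 4.45e-05, adjusted p = 0.110 with an estimated correlation). Fdps was 2.37-fold and Stard4 2.22-fold lower. Fatty acid synthesis was lower as well, where 0 members were higher and 7 were lower, with 7 of 14 not passing, also when adjusted over the list alone (camera adjusted p = 0.0159, adjusted p = 0.266 with an estimated correlation). Scd2 was at 377 ± 25.5 CPM under IL-4 and 73.5 ± 7.56 under IL-27, and the list call was lost without IL-4 replicate 1 and without both deviating libraries (camera adjusted p = 0.0538 and 0.0651).

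Glycolysis genes were split, where 5 of 26 tested members were higher, 10 were lower and 11 did not pass, or 7 and 13 adjusted over the list alone (camera adjusted p = 0.290). Pfkfb3 was 3.64-fold and Eno2 2.28-fold higher under IL-27 and Pdk1 and Pfkfb4 2.79-fold and 2.48-fold lower. In the pentose phosphate and antioxidant list 2 members were higher and 7 were lower, with 13 of 22 not passing, also when adjusted over the list alone (camera adjusted p = 0.666). Slc7a11 was 5.01-fold higher and Gpx1 and Tkt 2.00-fold and 1.97-fold lower. The list's median of 0.02, opposite in sign to the mean of -0.09 and to the test, turned with the scaling. In arginine and polyamine metabolism of 19 tested members 6 were higher, 5 were lower and 8 did not pass, also when adjusted over the list alone (camera adjusted p = 0.762). Gatm was 33.9-fold and Slc7a2 7.38-fold lower and Slc7a1 2.53-fold higher. Serine and one-carbon genes gave 5 higher and 9 lower of 18, also adjusted over the list alone (camera adjusted p = 0.207), the thymidylate gene Tyms being 7.10-fold lower and Slc1a4 3.65-fold higher. For ribosome biogenesis 2 of 28 tested members were higher, 8 were lower and 18 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0614). Myc was 3.52-fold lower, and the list reached a call without IL-4 replicate 1, with library size only and without a filter on low counts (camera adjusted p = 0.0485, 0.0334 and 0.0341). In the unfolded protein response and ATF4 list 12 members were higher and 9 were lower, with 3 of 24 not passing, or 13 and 10 adjusted over the list alone (camera adjusted p = 0.101). Trib3, Sesn2 and Atf4 were 5.82-fold, 3.24-fold and 2.22-fold higher and the endoplasmic reticulum enzyme Pdia4 3.06-fold lower, and library size only brought a list call (camera adjusted p = 0.0481).

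Hypoxia-induced genes were higher under IL-27: of 20 tested members 10 were higher, 1 was lower and 9 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00205, adjusted p = 0.110 with an estimated correlation). Vegfa was at 26.7 ± 2.22 CPM under IL-4 and 149 ± 11.1 under IL-27. Lysosomal genes were also higher, where 14 of 31 tested members were higher, 1 was lower and 16 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00229, adjusted p = 0.406 with an estimated correlation). Ctsk and Gla were 2.12-fold and 1.97-fold higher. Cholesterol efflux and LXR-linked genes gave 3 up and 3 down of 14, also adjusted over the list alone (camera adjusted p = 0.766). Mylip was 1.86-fold and the lipid carrier Apoe 1.76-fold higher. In macrophage identity genes 7 members were higher and 9 were lower, with 11 of 27 not passing, also when adjusted over the list alone (camera adjusted p = 0.766). Cd14 and Cx3cr1 were 3.66-fold and 3.69-fold higher. For pain-linked mediators of 24 tested members 6 were higher, 7 were lower and 11 did not pass, also when adjusted over the list alone (camera adjusted p = 0.862), Ptgs1 being 14.5-fold lower and Il1rn 8.87-fold higher under IL-27. The medians of the identity and pain lists, 0.16 and 0.11, were opposite in sign to their means, -0.04 and -0.03, and both tests pointed up. Fibroblast markers were higher under IL-27, where 8 of 10 tested members were higher, 1 was lower and 1 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.272 with an estimated correlation). Pdgfrb and Dcn were 5.38-fold and 6.01-fold higher. Immediate early and heat shock genes were lower, where 1 member was higher and 10 were lower, with 10 of 21 not passing, or 1 and 11 adjusted over the list alone (camera adjusted p = 0.00106, adjusted p = 0.153 with an estimated correlation). Ier3 and Hspa8 were 5.67-fold and 2.34-fold lower. Osteoclast markers gave 2 up and 4 down of 9 (3 and 4 adjusted over the list alone; camera adjusted p = 0.862; median 0.17, mean -0.54, test down), with Ocstamp 90.4-fold lower. Dendritic markers gave 2 up and 1 down of 7, also adjusted over the list alone (camera adjusted p = 0.862), with a median of -0.02 and a test pointing down against a mean of 0.13. In the granulocyte, mast cell and basophil, T and NK cell, B cell and erythroid lists 1 and 1, 1 and 0, 3 and 0, 1 and 1, and 0 and 0 members were up and down. Cd4, which macrophages can carry, stood at 4.30 ± 1.15 CPM under IL-4 and 12.1 ± 0.0708 under IL-27.

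Counting all genes, 2366 were higher and 2642 lower under IL-27 than under IL-4 by edgeR, 1050.0 and 984 of them by at least 2-fold, and camera called 14 lists, 6 up and 8 down. Alternative activation, interferon-gamma-type and cell cycle lists kept their calls with an estimated correlation. Higher genes made up 47.2% of these calls, 38.95% with library size only and 36.5% with limma on log2(FPKM + 1). FPKM values, like library size only, carry no TMM factors. Leaving out untreated replicate 2 and IL-4 replicate 1, chosen after seeing the data, gave 3560.0 higher genes, and at 2-fold or more limma called 425 and 583.

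Set against the same untreated libraries, 407 genes were higher under both cytokines and 471 lower under both, where independent lists of these sizes would share 229 in each direction. Simulated unchanged groups shared a mean of 0.05 and 0 over 20 data sets, but hardly any gene is called without an effect, so these values set no expectation for lists of this length. Another 393 genes were higher under IL-4 and lower under IL-27, against 247 for independent lists, and 312 lower under IL-4 and higher under IL-27, against 213. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.0895, while simulated unchanged groups gave 0.504 from the shared controls alone. Their covariance was 0.0528 against a simulated 0.0463, a difference of 0.00644. Only 3 control libraries exist, too few to split, so part of the excess in the same direction may come from the shared controls. Shared controls would not produce the excess in opposite directions. The expectation for independent lists takes every gene as equally likely to be called, so an excess over it does not by itself show a shared response. Slc40a1 and Adgre4 are examples of genes lower under both, with 161 ± 10.05 and 13.4 ± 2.88 CPM untreated, 13.2 ± 3.05 and 0.282 ± 0.321 CPM under IL-4 and 18.3 ± 0.635 and 1.11 ± 0.180 CPM under IL-27. Asns, Trib3, Mthfd2 and Slc7a1 rose under both, and all 4 were higher still under IL-27 than under IL-4 (log2 1.42 ± 0.11, 2.54 ± 0.14, 0.74 ± 0.09 and 1.34 ± 0.08). Leaving out the 2 deviating libraries gave 1014 genes higher and 1082 lower under both, GC offsets, also chosen after seeing the data, 715 and 818, and leaving out IL-4 replicate 3 alone 312 lower under both.

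**Figure D3:**
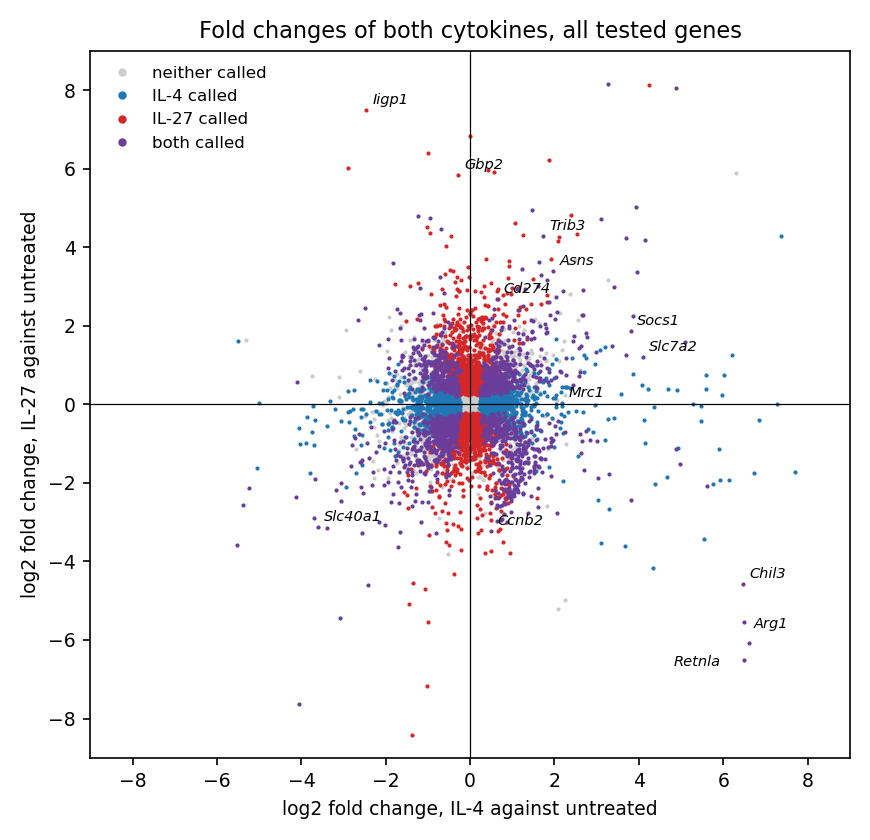
Log2 fold change of IL-27 against untreated (y axis) over that of IL-4 against untreated (x axis) for the 12587 tested genes, each point a gene, coloured by which edgeR adjusted p was under 0.05. Arg1, Chil3 and Retnla lie to the right and below, Gbp2 and Iigp1 at the top and Trib3, Asns and Slc7a2 in the quadrant of both rises.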

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

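The alternatives with both deviating libraries left out, GC offsets and carry-over subtraction were chosen after seeing the data, and for every difference below the cause was not tested. Of 486 gene results, 421 kept their call and direction in those of the 22 alternatives that tested them, and 0 reversed. These results cover the named genes, many picked in the main fit for large fold changes or small adjusted p, so most were likely to hold. Over all genes called in the main fit, the share kept was lower in some settings. For IL-4 against untreated it was 67.4% with only the 2 groups fitted, 73.1% with a replicate block and 99.9% with DESeq2. For IL-27 against untreated it was 69.4% without IL-27 replicate 1. Not every alternative tested every gene, and with CPM over 1 in 3 libraries 457 results could be compared. Of 84 list results over up to 19 alternatives, 28 kept theirs and 2 reversed. With untreated replicate 2 and IL-4 replicate 1 left out, 3061 genes were higher and 2848 lower under IL-4, 3089 and 3224 under IL-27, 3560.0 higher under IL-27 than under IL-4, and 1014 higher and 1082 lower under both. GC offsets gave 2508 and 2357 under IL-4, and 715 and 818 under both. Fitting only the 2 groups compared called 2138 genes under IL-4, 984 of them lower. Limma on log2(FPKM + 1), whose pseudocount shrinks fold changes of low genes, called 262 and 144 genes at least 2-fold under IL-4, 234 and 288 under IL-27 and 425 and 583 between the cytokines. With the filter of FPKM over 0 it called 259, 144, 231, 287, 425 and 584. With log2(FPKM + 0.1) it called 239 at least 2-fold lower under IL-4, 361 higher under IL-27 and 599 higher between the cytokines. Camera with an estimated correlation called 6, 3 and 3 lists, and fry called 18 lists for IL-27 against untreated and 22 for IL-27 against IL-4. The 2 reversals were the signalling list under fry, for IL-4 against untreated (median -0.0688, fry adjusted p = 0.000769) and for IL-27 against IL-4 (median 0.105, fry adjusted p = 0.00268), where camera made no call. DESeq2 called 3715, 4288 and 5478 genes. Leaving out each library in turn gave 1214 to 1827 higher and 1066 to 1839 lower genes under IL-4 (at least 2-fold 473 to 510.0 and 377 to 495, lists 15 to 17). Under IL-27 it gave 1241 to 2232 and 1335 to 2386 (488 to 630.0 and 608 to 683, lists 11 to 12), and 1869 to 2644 and 1961 to 3056 between the cytokines (917 to 1060.0 and 917 to 1015, 14 lists each time). The number higher under both ranged from 278 to 531 and lower under both from 312, without IL-4 replicate 3, to 660.0. Libraries of the same replicate number in untreated and IL-4 deviated from their group means with correlations of -0.78, -0.80 and 0.67. Between untreated and IL-27 the correlations were 0.01, 0.06 and 0.05, and between IL-4 and IL-27 0.03, -0.01 and 0.08. Not every library correlated best with its own number. Deviations within a group cancel out, so the deviation shared by untreated replicate 2 and IL-4 replicate 1 largely set the signs between those groups. These correlations therefore cannot decide whether the replicate numbers pair untreated and IL-4 samples, and those with IL-27 showed little sign of pairing. A replicate block gave 1207 and 1101 genes, 1399 and 1500.0, and 2034 and 2182 in the 3 comparisons, 276 and 321 under both, and took 15 gene calls and 2 list calls away. No setting tried separates time from cytokine, shows whether IL-27 cells also saw IL-4, or measures protein, metabolites or pain. The alternative activation list rose under IL-4 and was not called by camera under IL-27. That argues against IL-4 having acted in the IL-27 cells as it did in the IL-4 libraries, but not against IL-4 having been given without such an effect.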

Other observations

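Slc40a1, Clec4n, Tlr2 and Hpgd were among the 8 largest falls of a comparison, and the other genes in this paragraph and the next were chosen after their values were seen. All lay outside the fixed lists, and no cause was tested. The transferrin receptor Tfrc rose by 2.17 ± 0.20 under IL-4 (log2, edgeR adjusted p = 5.10e-05) and did not pass under IL-27 (-0.05 ± 0.19), where it passed with both deviating libraries left out or with GC offsets (edgeR adjusted p = 0.00617 and 0.00732). The exporter Slc40a1 was lower under both (-3.61 ± 0.16 and -3.13 ± 0.15), Slc11a1 and the ferritin gene Fth1 were lower under IL-4 (-1.64 ± 0.15 and -0.79 ± 0.15), and the ferroxidase Cp was higher under IL-27 (1.68 ± 0.24, edgeR adjusted p = 0.000626). Clec4e, Clec4d, Clec4n, Tlr2, Tlr7 and Tlr9 were each lower under IL-4 (-2.66 ± 0.32, -2.59 ± 0.11, -4.09 ± 0.20, -2.87 ± 0.17, -1.74 ± 0.29 and -1.85 ± 0.20), while Clec4e was higher under IL-27 (2.14 ± 0.28).

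The thromboxane synthase Tbxas1 rose under IL-4 (1.26 ± 0.13), Hpgd fell under both (-2.43 ± 0.21 and -4.61 ± 0.23), and Pla2g7 fell under IL-4 (-1.22 ± 0.19) and rose under IL-27 (1.02 ± 0.19). Under IL-27 the activin subunit Inhba rose by 3.11 ± 0.16, the plasminogen activator Plau by 1.73 ± 0.13, and the protease inhibitors Timp1 and Timp3 by 1.75 ± 0.12 and 2.46 ± 0.12 (edgeR adjusted p = 1.49e-06, 8.51e-06, 7.40e-06 and 1.19e-06).

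For the libraries that stood apart, the tests of transcript length and of an exchange of libraries were chosen only after the result was seen. Untreated replicate 2 and IL-4 replicate 1 deviated from their groups in the same genes (r = 0.900), and the deviations followed transcript GC content (Spearman 0.740 and 0.769). GC content alone, were it measured exactly, would leave no correlation within bins of equal GC, but r was 0.772 within 20 such bins. The mean SD of the deviations in both libraries fell from 0.2921 to 0.1925 within these bins. Within bins of gene length r was 0.895 and the mean SD 0.2855, so gene length is not the whole cause. GC values came from the longest transcript in an older annotation, so the correlation left within bins cannot exclude GC content as the whole cause. An exchange of these libraries is argued against by Arg1, at least 74.0-fold higher in IL-4 replicate 1 than in any untreated library. RNA quality, library preparation and a shared culture or day could each leave such a pattern, none was tested, and they stay open.

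For Arg1, Chil3 and Retnla below the untreated level under IL-27, the wider gene set, the share of cells and the transcript proportions were tested only after the result was seen. Mean untreated levels of these 3 genes lay near 1% of the IL-4 level, and about 1% of IL-4-treated material in the untreated libraries could produce that. The test on 3 genes (0% under the bound) was void because it held only the pattern's own genes. Over 19 genes the mean untreated level ranged from 0.843% to 14.9% of the IL-4 level, with 6 genes between 0.8% and 1.2%. Carry-over and a small share of fully activated cells both predict such a lowest level. It rests partly on few counts, and single libraries differed. Rnase2a stood at 0.379%, 0.966% and 1.63% in the 3 untreated libraries, from 3, 8 and 13 counts. Of 6 untreated proportions of Retnla or Arg1 to Chil3, 3 lay outside the range of the IL-4 libraries but 0 with their whole exact 95% interval. Subtracting that lowest share, 0.843%, moved the log2 fold changes under IL-27 from -5.54 to -3.39 for Arg1, -4.58 to -2.47 for Chil3 and -6.50 to -4.43 for Retnla. Of these, Retnla alone no longer passed (edgeR adjusted p = 0.0276, 0.0218 and 0.0857). Untreated Arg1, Chil3 and Retnla stood at 1.09%, 1.10% and 1.08%, so part of their untreated level was bound to remain. The calls that remained therefore cannot exclude carry-over. Carried-over material, a few activated cells and a fall caused by IL-27 all stay open, and qPCR on separately prepared untreated cells could test for carried-over material.

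For the fibroblast markers, higher under IL-27 than in untreated libraries, both tests were chosen only after the result was seen. The collagen genes Col1a1, Col1a2 and Col3a1 together rose by 378 CPM, more than Dcn, but from far higher levels almost any rise would be, so that test was void. A higher share of the same fibroblasts, or of their RNA, is argued against as the only cause by Postn, whose ratio of IL-27 to untreated was 0.839, with at most 35.5 CPM in an IL-27 library where 53.5 CPM would be needed to match the ratio of Col1a1. The ratios of Col1a1 (1.41), Col1a2 (1.61), Col3a1 (2.03), Pdgfrb (2.33) and Dcn (4.42) were also unequal. Fibroblast RNA of another make-up, a response of fibroblasts already in the cultures and a response of the macrophages stay open.

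Splitting the 6 libraries of each comparison in all 10 ways gave 2138, 4096 and 5150.0 called genes for the real groups of the 3 comparisons and at most 0 for any other split, so 1 split reached the real number each time. With 10 splits the share cannot fall under 0.05, so this test could not settle the matter.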
